A study of Mus musculus with 12 samples.

How the data were processed

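RNA-seq counts were compared between 12 libraries of MC38 tumours, a mouse colon carcinoma line grown under the skin of C57BL/6J mice. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra kit. Per the submitters' processing notes, the tools named were HISAT2 2.1.0, StringTie 1.3.5 and DESeq2, with genome build GRCm38. The role of each tool, the annotation release, the strand setting and any filter on genes are not given in the sources used here. The deposited values were whole-number counts per gene, not normalised, in a table of all libraries. Each of the 12 per-library files held the same values as its column of that table. The table had 43698 rows and 42803 distinct gene names, and 35987 of those names were found in the RefSeq gene table used for coordinates. Because the use of strand is not stated, counts of overlapping or antisense genes cannot be told apart. Reads of near-identical gene copies could have been split or lost, so such genes are named as uncertain.

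Groups came from the agent label. RP was read as the antibody-catalyst conjugate Ru-PD-L1, which targets the checkpoint ligand PD-L1. R+X was read as Ru-PD-L1 with DOX, because the letter X occurs only in DOX, and R+D as Ru-PD-L1 with DPD, the combination that was left. If these readings were exchanged, the values given for R+X and R+D would change places. DPD was read as the DOX (doxorubicin) prodrug of the series title. The labels number no replicates, so replicates 1 and 2 name the libraries of a group in order of listing and pair nothing. They do not state that the libraries of a group came from separate mice, so p-values measure the spread between these samples, which may be technical.

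Counts were analysed in R 4.3.3. One edgeR 4.0.16 quasi-likelihood fit held all 12 libraries in 6 groups, with TMM scaling and filterByExpr, which left 19525 genes tested. The spread was shared over the groups, with 6 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and errors of log2 fold changes are standard errors from the same test. Contrasts compared each treatment with Ctrl, DPD with DOX, R+D with R+X, each combination with its parts, the conjugate's effect with and without each drug, and the conjugate averaged over the drug settings. Levels are CPM, counts scaled with TMM to a common library size, with the SD of 2 libraries. Total counts were 46547114 to 56462259 per library, and the biological coefficient of variation was 0.257.

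Gene lists, the rule for naming genes and the tests were written before the data were examined. The 32 lists with at least 5 tested members covered drug response, interferon and antigen presentation, immune and stromal cell types, metabolism, and tissues that can be taken along with a tumour. They were tested with limma 3.58.1's camera at a preset correlation of 0.01 on log2 CPM (prior count 2), adjusted over the lists of a comparison. A list of mitochondrial genome genes had 0 members in the table and was left out. Beside the calls stand values of camera with an estimated correlation. Per comparison the text gives the number of lists called by fry, which tests whether the members move on balance one way, and by a limma test of the list mean per library, chosen after seeing the data. Medians of called lists are given where leaving out 1 library ended the call or moved them by over 1.5 times, with the adjusted p where the call ended, and so are values of single genes moved by over 1.5 times. The same holds for the muscle covariate. In all 15 comparisons, 0 lists passed camera with an estimated correlation. Per comparison the text names called genes with non-overlapping groups and a mean of at least 1 CPM. Where fewer than 5 passed, it gives values for up to 3 genes of smallest p each way under the same conditions, up to 4 members of smallest p in a list discussed, and a fixed panel of immune and drug-response genes. Predicted genes, unnamed loci and name copies with a suffix were counted but not named.

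Simulated counts modelled on the means and spreads of these libraries tested the method for RP against Ctrl (19061 genes, 5 simulations). The edgeR test called 8% of genes changed 1.5-fold, 36.4% of those changed 2-fold, 80.8% 4-fold and 95.2% 8-fold. It called 25 of 94166 unchanged genes. The T cell list raised 2-fold was called in 5 of 5 simulations, with genes drawn independently. Unchanged simulations called 0 lists but regrouped real libraries (averaged conjugate) a median of 8, so these rates may not carry over.

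Alternatives were RLE scaling, no low-count filter, DESeq2 1.42.0, each library left out in turn, the 2 compared groups alone, an additive fit and an estimated correlation. Added after seeing the data were limma-voom, summed name copies, a skeletal muscle or skin score as a covariate, list means, and fits without libraries of other groups. A library left out of a group of 2 leaves a lone library that is assumed to vary like the other groups. Length and GC content were found for 83.2% of the genes tested and all list members. Gene coordinates are those of GRCm38.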

Results

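Tumours of the mouse colon carcinoma line MC38 were profiled by RNA-seq in 6 groups of 2 libraries each. Mice of 8 weeks received PBS (Ctrl), 14 µg of DOX, 14 µg of DPD, or 20 µg of the conjugate Ru-PD-L1 (RP) by intraperitoneal injection, every 3 days from day 9. The combined groups received the conjugate (dose not stated) and, 6 hours later, 14 µg of DOX (R+X) or DPD (R+D) beside the tumour. Tumours were taken on day 20. Only combined groups were injected beside the tumour, so drug route and this injection changed with the combination. Library totals ran from 46547114 counts in R+D replicate 2 to 56462259 in RP replicate 2. Libraries of one group differed by far more than counting noise, with a chi-square per degree of freedom from 13.5 in R+X to 216 in DOX.

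Libraries did not lie closest to the other library of their group. The median correlation of log2 CPM was 0.9753 within groups and 0.9745 between groups, and 0 of 12 libraries had its own mate as nearest neighbour. Differences within groups held 49.7% of the variance, against 54.5% for a random arrangement. No test of these values was run.

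What the conjugate alone changed was asked by comparing RP with Ctrl. In edgeR 3 genes rose: Gja4, which encodes the gap junction protein connexin 37, Serpina3g, a serine protease inhibitor gene, and Apol10b of the apolipoprotein L family. Gja4 rose by 2.29 ± 0.28 log2 units, from 7.35 ± 0.317 to 36 ± 6.06 CPM (edgeR adjusted p = 0.0458). Apol10b rose by 1.69 ± 0.18, from 7.56 ± 0.774 to 24.3 ± 0.984 CPM, and Serpina3g by 1.44 ± 0.16, from 48.8 ± 6.83 to 132 ± 2.64 CPM (edgeR adjusted p = 0.0294 for both). Interferon gamma response genes rose as a list (median 1.46), with T cell (1.34), cytotoxic effector (1.299) and regulatory T cell markers (1.54). Camera called each of these lists at the preset correlation (adjusted p from 2.45e-16 to 0.00177) and none with an estimated correlation (adjusted p = 0.342 for each). Without RP replicate 1 the median was T cells 0.88. With the muscle score as a covariate the medians were T cells 0.23 and regulatory T cells 1.03 (adjusted p = 0.0604). On GRCm38, Gja4 lies on chromosome 4 from 127311420 to 127314039, Serpina3g on chromosome 12 from 104236147 to 104241939, and Apol10b on chromosome 15 from 77584154 to 77598542, all annotated as protein coding. Serpina3g sits among near-identical copies and Apol10b in a gene family, so their counts may include reads of relatives. In edgeR 0 genes fell, with 1831 lower at an unadjusted p under 0.05, and those of smallest p were Nr2f1 (-1.17 ± 0.19), Slc14a1 (-1.32 ± 0.25) and Tes (-0.79 ± 0.15), with edgeR adjusted p from 0.088 to 0.127. DESeq2 called 750 genes higher and 461 lower, limma-voom 16 genes and edgeR with only these groups 505. All 3 edgeR calls were lost when any 1 library of RP or Ctrl was left out, and with a skeletal muscle score as a covariate.

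**Figure D1:**
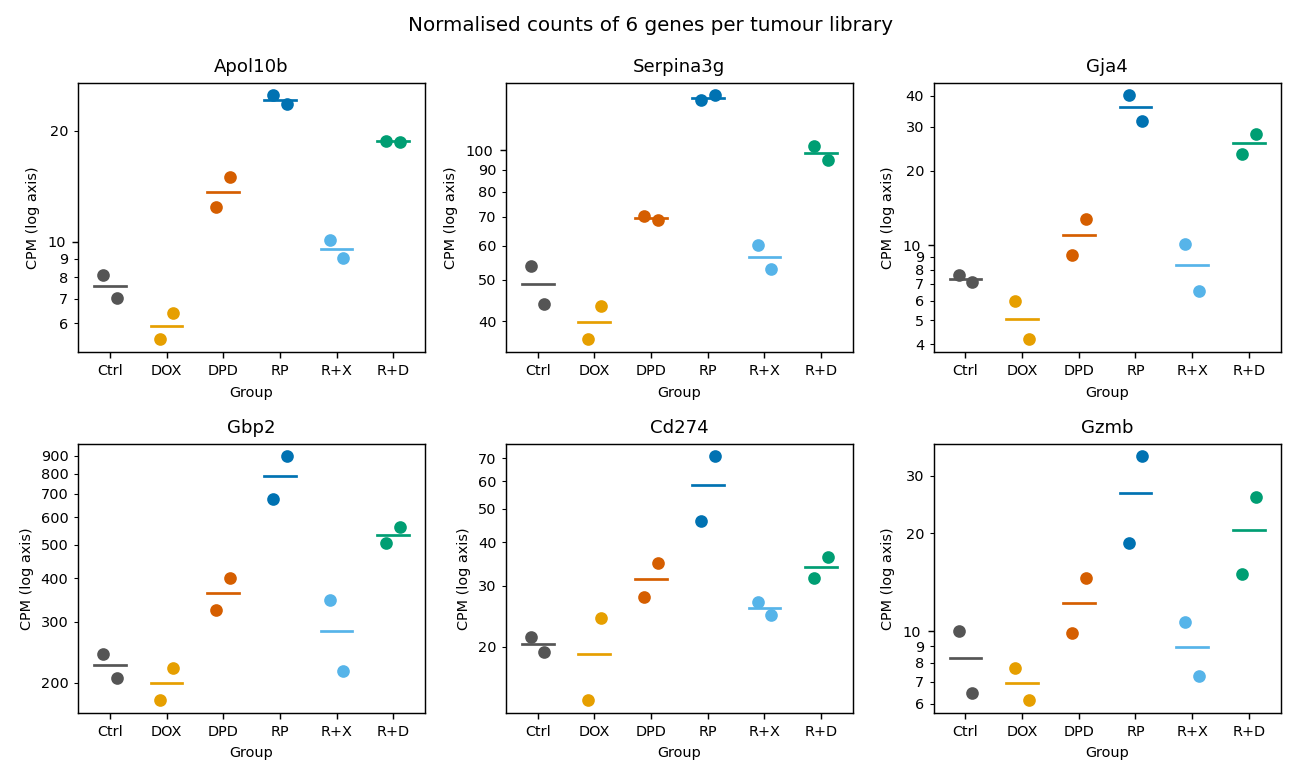
Normalised counts (CPM, log axis, each panel with its own range) of 6 genes in the 12 tumour libraries by group; points are libraries and lines group means. Gja4 stood at 36 ± 6.06 CPM in RP and 25.7 ± 3.46 in R+D against 7.35 ± 0.317 in Ctrl (mean ± SD, n = 2), while Cd274 and Gzmb did not pass edgeR in any comparison and passed DESeq2 in RP against Ctrl.

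Of the 26 interferon gamma response genes, 1 passed edgeR over all genes tested and 25 when adjusted over the list alone. They included Gbp2, a guanylate-binding protein gene (1.81 ± 0.24), Gbp4 (2.53 ± 0.38), Gbp5 (2.31 ± 0.36) and Cd274, which encodes PD-L1 (1.52 ± 0.28; 58.5 ± 17.7 against 20.3 ± 1.49 CPM), with edgeR adjusted p from 0.0565 to 0.127. The list mean per library rose by 1.46 (95% interval 0.87 to 2.05), with a limma adjusted p = 0.0302; camera gave an adjusted p = 2.45e-16 at the preset correlation and adjusted p = 0.342 with an estimated correlation. Gbp genes have close copies and their single values are uncertain. Among genes of MHC class I presentation (median 0.33), Tap1 (0.81 ± 0.22) and Tapbp (0.66 ± 0.17) were 2 of the 7 of 18 that passed when adjusted over the list alone. That list's camera adjusted p = 0.0214 became adjusted p = 0.546 with an estimated correlation, and its call was lost without Ctrl replicate 1 (0.28, adjusted p = 0.101) or RP replicate 1 (0.22, adjusted p = 0.188). With the muscle covariate its median was -0.00839 (adjusted p = 0.823) and Tap1 stood at 0.45. MHC class II presentation (median -0.27, camera adjusted p = 0.167) and the type I interferon response (0.0873, camera adjusted p = 0.178) were not called.

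Markers of lymphocytes were higher in RP, where muscle transcripts were higher too. All 21 T cell genes had positive fold changes and 9 passed when adjusted over the list alone, among them Icos (2.28 ± 0.51) and Cd3g (1.44 ± 0.39). All 21 cytotoxic effector genes were positive and 15 passed that way, with Prf1, the perforin gene, at 1.87 ± 0.39. Gzma (2.12 ± 0.49) and Gzmb (1.69 ± 0.39) belong to a family of close copies and are uncertain. Regulatory T cell markers, among them Foxp3 (1.87 ± 0.48), Tnfrsf18 (1.81 ± 0.41) and Il2ra (1.65 ± 0.47), passed in 4 of 8 members when adjusted over the list alone, and checkpoint genes (median 0.83) in 4 of 12. Camera's adjusted p was 5.16e-07 for T cells, 9.02e-09 for cytotoxic effectors, 0.00177 for regulatory T cells and 0.000332 for checkpoints, and for each the adjusted p = 0.342 with an estimated correlation. B and plasma cell markers (median 0.98; Jchain 3.16 ± 0.98; 3 of 9 passing when adjusted over the list alone) rose with a camera adjusted p = 0.0334, or adjusted p = 0.404 with an estimated correlation, and the call was lost without single libraries. With Ctrl replicate 1 left out it was B cells 1.62 (adjusted p = 0.0878). The medians without RP replicate 1 were B cells 0.92 (adjusted p = 0.14) and T cells 0.88. Leaving out RP replicate 2 gave a median of B cells 1.59. The fit with the muscle covariate gave B cells -0.33 (adjusted p = 0.777), T cells 0.23, regulatory T cells 1.03 (adjusted p = 0.0604) and checkpoints 0.51 (adjusted p = 0.0796), and Icos stood at 1.48, Cd3g 0.70, Gzma 1.16 and Jchain 1.36.

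**Figure D2:**
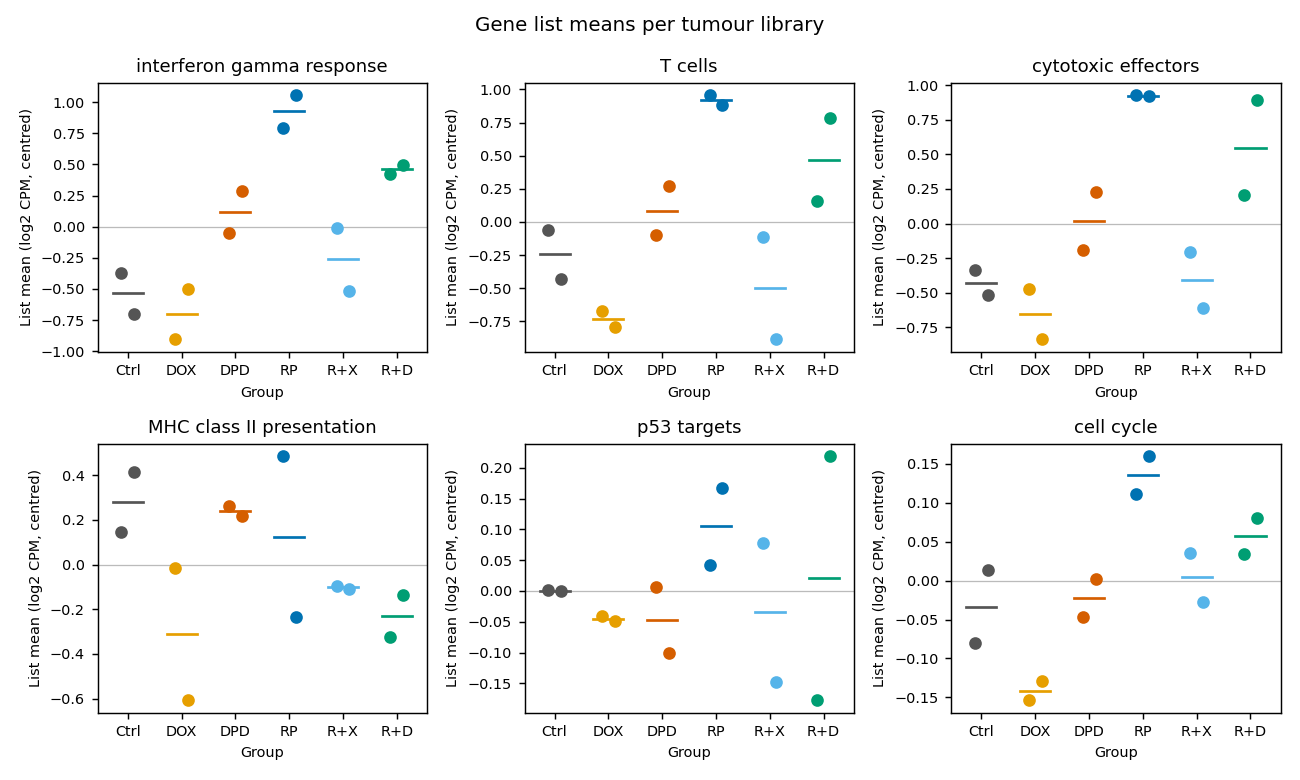
Mean log2 CPM of 6 gene lists in each library, centred on the mean of the 12 libraries, by group; points are libraries and lines group means, and each panel has its own range. For the interferon gamma response the RP libraries sat at 0.79 and 1.06 and the Ctrl libraries at -0.37 and -0.70.

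Myeloid and stromal markers moved less evenly in RP. Neutrophil markers (median 1.05) rose with Csf3r, the G-CSF receptor gene, at 2.20 ± 0.33, while Mmp9 was at -1.11 ± 0.28; camera's adjusted p = 0.00997 became adjusted p = 0.415 with an estimated correlation. Dendritic cell markers (median 0.85; Flt3 2.43 ± 0.59, Irf8 0.66 ± 0.16) rose with a camera adjusted p = 0.00221, or adjusted p = 0.342 with an estimated correlation. Endothelial markers (median 0.49; Pecam1 0.85 ± 0.18, Vwf 1.16 ± 0.32) and inflammatory cytokines (median 0.93; Lif 1.17 ± 0.25) rose with camera adjusted p = 0.000278 and 0.001, which became adjusted p = 0.342 and 0.404 with an estimated correlation. Without RP replicate 1 the medians were dendritic cells 0.53 (adjusted p = 0.146) and endothelial cells 0.27. With RP replicate 2 left out they were neutrophils 0.37 (adjusted p = 0.0933) and inflammatory cytokines 0.30. Medians with the muscle covariate were neutrophils 0.53 (adjusted p = 0.16), dendritic cells 0.33 (adjusted p = 0.201) and inflammatory cytokines 0.42 (adjusted p = 0.0796), and Pecam1 stood at 0.53 and Vwf 0.55. RP replicate 2 was also the library richest in skin transcripts (list mean 2.90, against -1.22 in RP replicate 1), and within groups the neutrophil and inflammatory means moved with that of skin (r = 0.84 and 0.71). With a skin score as a covariate, added after seeing the data, these medians were 0.85 and 0.79 (camera adjusted p = 0.00973 and 0.0016). When adjusted over the list alone 5 of 17 neutrophil, 4 of 16 dendritic, 4 of 16 endothelial and 4 of 20 inflammatory genes rose. Macrophage (0.24), fibroblast (0.24), mast cell (0.24), adipocyte (0.27), epithelial (-0.33), skin (1.92) and senescence-associated lists (0.33) were not called, with camera adjusted p from 0.124 to 0.916.

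Skeletal muscle transcripts stood apart in some libraries of the conjugate groups. The muscle list rose in RP (median 2.70; Mb 3.25 ± 0.86, Tnnc2 2.98 ± 0.71; 18 of 20 passing when adjusted over the list alone; camera adjusted p = 8.94e-07, or adjusted p = 0.404 with an estimated correlation). Summed over the list, muscle transcripts reached 410 CPM in RP replicate 1, 203 in RP replicate 2 and 499 in R+D replicate 2, against 117 and 142 in Ctrl. With a muscle score as a covariate, chosen after seeing the data, 0 genes passed edgeR in RP against Ctrl and Gja4 stood at 1.85. In that fit 11 lists were called in place of 17, and Tnnc2 stood at 0.82 and Mb at 0.60. With RP replicate 1 left out Mb stood at 2.08.

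Ribosomal protein genes fell in RP (median -0.82), as did oxidative phosphorylation (-0.57), ER stress (-0.41) and red blood cell genes (-1.80). All 24 ribosomal protein genes were negative and 17 passed when adjusted over the list alone (Rps14 -1.25 ± 0.36). Among oxidative phosphorylation genes, Ndufb5 (-0.75 ± 0.25) and Sdhb (-0.76 ± 0.24) had values of this size, and 0 of 24 passed that way. Of 21 ER stress genes 5 did, among them Herpud1 (-0.79 ± 0.16), Xbp1 (-0.77 ± 0.20) and Asns (-0.64 ± 0.17), which encodes asparagine synthetase. Haemoglobin genes, which mark blood in the sample and have close copies, were at -1.82 ± 0.57 for Hba-a1 and -1.86 ± 0.59 for Hbb-bs, and 6 of 6 of the list passed that way. At the preset correlation, the adjusted p of camera was 5.77e-09 for ribosomal proteins, 1.37e-06 for oxidative phosphorylation, 3.34e-05 for ER stress and 0.000313 for red blood cells, and the adjusted p = 0.404, 0.41, 0.342 and 0.342 with an estimated correlation. The medians without Ctrl replicate 2 were ribosomal proteins -0.44 and oxidative phosphorylation -0.29, and Rps14 stood at -0.65, Ndufb5 -0.39 and Sdhb -0.44. Fold changes of all genes rose with transcript length (Spearman rho = 0.34), and after a length and GC trend was removed the medians were ribosomal proteins -0.62, oxidative phosphorylation -0.41 and ER stress -0.36.

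DNA repair genes rose as a list in RP (median 0.27; Brca2 0.86 ± 0.22; camera adjusted p = 0.0334, or adjusted p = 0.404 with an estimated correlation). That call was lost without Ctrl replicate 1 (0.25, adjusted p = 0.13) or RP replicate 2 (0.17, adjusted p = 0.12). The p53 targets had a median of 0.0439 (camera adjusted p = 0.922), with Cdkn1a, the p21 gene, at -0.17 ± 0.20 (-0.27 without RP replicate 1) and Btg2 at 0.93 ± 0.20. Cell cycle genes had a median of 0.0507 (camera adjusted p = 0.167), although Mki67 stood at 1.27 ± 0.29 and Top2a, the DOX target topoisomerase II alpha, at 0.80 ± 0.21. Apoptosis (-0.17), immediate early (-0.25), NRF2 (-0.0559) and hypoxia genes (-0.12) were not called, with camera adjusted p from 0.157 to 0.417.

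Over all genes, 3 passed edgeR in RP against Ctrl, while 4182 had an unadjusted p under 0.05 where chance gives 976. DESeq2 called 1211. For lists, beside camera's 17, fry called 12 lists and the list means 8 (smallest limma adjusted p = 0.0302). In fits added after seeing the data, the edgeR count also moved when libraries of other groups, which share the estimate of the spread, were left out. It was 46 without DOX replicate 1, 48 without DOX replicate 2, 36 without both, 5 without DPD replicate 1, 5 without DPD replicate 2, and 0 without R+X replicate 1, R+X replicate 2, R+D replicate 1 or R+D replicate 2.

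**Figure D3:**
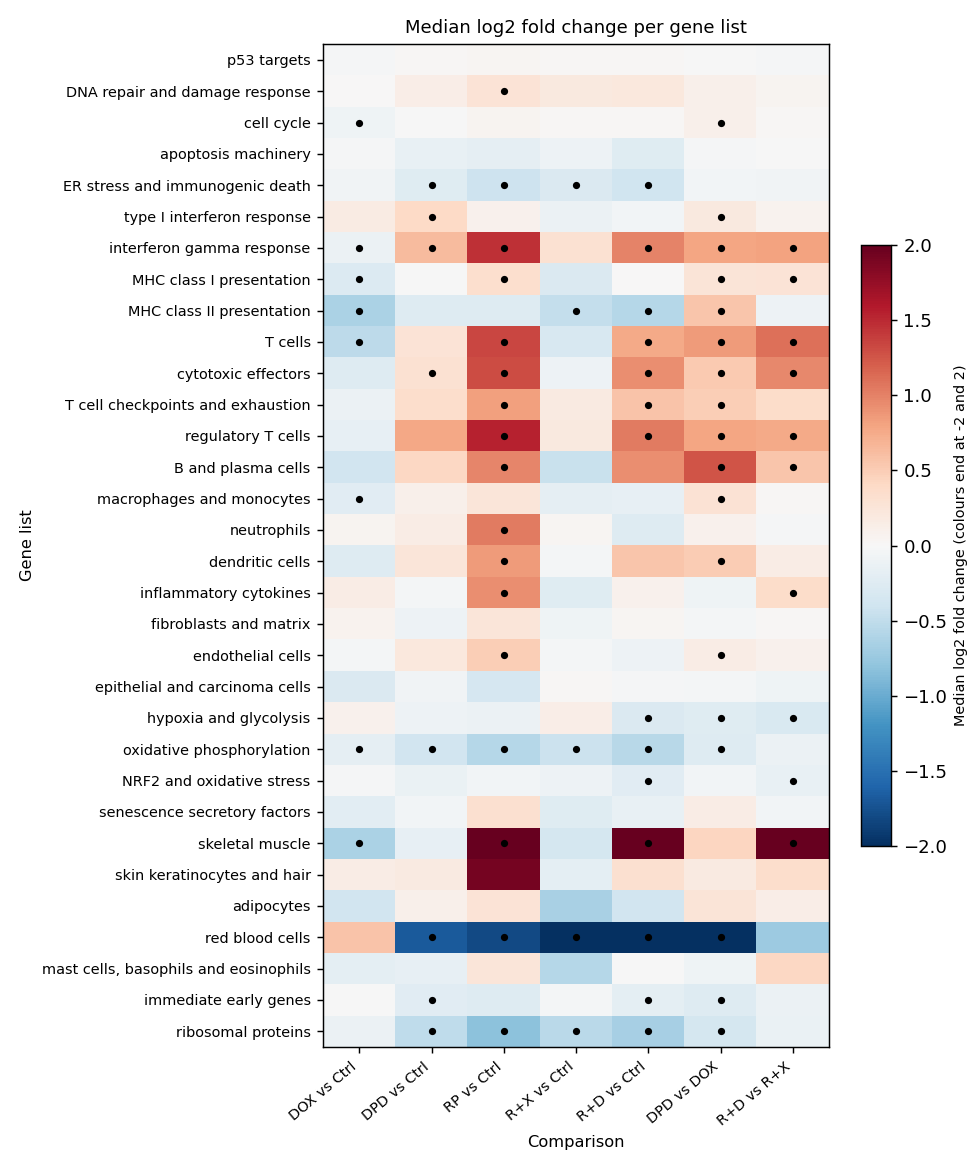
Median log2 fold change of each gene list (vertical axis) in 7 comparisons (horizontal axis), with red for higher and blue for lower values and colours that end at -2 and 2; black dots mark lists called by camera at the preset correlation. The interferon gamma list had a median of 1.46 in RP, 0.98 in R+D, 0.63 in DPD, 0.30 in R+X and -0.12 in DOX against Ctrl; with an estimated correlation 0 lists were called.

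With DOX alone 0 genes passed edgeR (1 without DOX replicate 2, 1 without the low-count filter and 2 with only these groups), 407 had an unadjusted p under 0.05, fewer than the 976 of chance, and DESeq2 called 1. Camera called 8 lists lower at the preset correlation and 0 with an estimated correlation (adjusted p from 0.713 to 0.817), while fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.859). MHC class II genes fell (median -0.64), with Cd74, the invariant chain, at -0.84 ± 0.23, H2-Aa at -0.91 ± 0.26 and H2-Eb1 at -0.91 ± 0.27, and 3 of 11 passed when adjusted over the list alone. T cell genes fell (median -0.53; Cd3e -1.18 ± 0.36, Zap70 -0.87 ± 0.32), as did those of MHC class I (-0.27), macrophages (-0.22; Lyz2 -0.29 ± 0.16) and the interferon gamma response (-0.12; Cxcl9 -0.66 ± 0.35). Cell cycle genes were lower by a small amount (-0.0899; Rrm2 -0.39 ± 0.15), as were oxidative phosphorylation (-0.18) and muscle genes (-0.63). In these lists 0 members other than the MHC class II ones passed when adjusted over the list alone. Camera's adjusted p ran from 4.45e-07 for MHC class II to 0.0305 for muscle, and each call was lost when some single library was left out, as given below. The p53 targets had a median of -0.0191 (camera adjusted p = 0.692), with Cdkn1a at -0.18 ± 0.20 and Top2a at 0.11 ± 0.20. Cd274 stood at -0.0912 ± 0.27. Without Ctrl replicate 1 Top2a stood at 0.21 and Cd274 -0.012. In fits without Ctrl replicate 2 Lyz2 stood at -0.19, Top2a 0.0237 and Cd274 -0.16. When DOX replicate 1 was left out Lyz2 stood at -0.48, Cxcl9 -0.38, Cdkn1a -0.55, Top2a 0.33 and Cd274 0.25. With DOX replicate 2 left out Lyz2 stood at -0.13, Cxcl9 -0.9959, Cdkn1a 0.12, Top2a -0.13 and Cd274 -0.54. Fold changes rose with transcript length (Spearman rho = 0.35), and the oxidative phosphorylation median was -0.10 after a length and GC trend was removed.

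Each of the 8 DOX list calls was lost when some single library was left out. The count of 8 fell to 5 without Ctrl replicate 1 and to 4 without DOX replicate 2. Leaving out Ctrl replicate 1 gave medians of T cells -0.43 (adjusted p = 0.1), macrophages -0.22 (adjusted p = 0.102), interferon gamma 0.0613 (adjusted p = 0.811), oxidative phosphorylation -0.37 and muscle -0.58 (adjusted p = 0.433). Without Ctrl replicate 2 the medians were interferon gamma -0.28, cell cycle -0.0291 (adjusted p = 0.293) and oxidative phosphorylation 0.0656 (adjusted p = 0.811). With DOX replicate 1 left out they were MHC class II -0.998, MHC class I -0.65, macrophages -0.43, interferon gamma 0.0761 (adjusted p = 0.9), cell cycle -0.14 (adjusted p = 0.21), oxidative phosphorylation -0.53 and muscle -1.21 (adjusted p = 0.21). The medians without DOX replicate 2 were MHC class II -0.38 (adjusted p = 0.0532), MHC class I 0.0431 (adjusted p = 0.984), macrophages -0.0368 (adjusted p = 0.319), interferon gamma -0.37, cell cycle -0.077 (adjusted p = 0.0804), oxidative phosphorylation 0.0742 (adjusted p = 0.311) and muscle -0.70 (adjusted p = 0.332). With the muscle score as a covariate the medians were MHC class I -0.18, interferon gamma -0.11 (adjusted p = 0.0517) and muscle -0.076 (adjusted p = 0.837). Genes of smallest p in edgeR were Pakap (4.91 ± 0.65), Dpyd (1.28 ± 0.38) and Matn2 (0.54 ± 0.16) on the higher side. Rmi2 (-0.76 ± 0.18), Napsa (-1.18 ± 0.29) and Serping1 (-1.22 ± 0.34) were those on the lower side. Pakap shares its locus and reads with Akap2 and Palm2, and its values are uncertain in every comparison.

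By camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.583 for each called list), DPD alone raised interferon lists. The interferon gamma response rose (median 0.63), with Gbp2 at 0.69 ± 0.24, Gbp4 at 1.10 ± 0.36, Ido1 at 1.34 ± 0.47, Serpina3g at 0.51 ± 0.16 and Cd274 at 0.63 ± 0.27. Type I interferon genes (median 0.41; Oas2 0.86 ± 0.34, Oas3 0.88 ± 0.32, Zbp1 0.54 ± 0.17) and cytotoxic effectors (0.30; Klrk1 0.88 ± 0.31) rose too. Ribosomal (-0.51), oxidative phosphorylation (-0.39), red blood cell (-1.68; Hba-a1 -1.65 ± 0.57, Hbb-bs -1.71 ± 0.59), immediate early (-0.23; Egr3 -0.68 ± 0.20) and ER stress genes (-0.24) fell. Adjusted over the list alone, 6 of 6 red blood cell genes passed and 0 in the other lists. At the preset correlation, the adjusted p of camera ran from 2.82e-10 for the interferon gamma response to 0.0137 for ER stress, while fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.448). Leaving out Ctrl replicate 1 gave medians of cytotoxic effectors 0.53, ribosomal proteins -0.78, oxidative phosphorylation -0.63 and immediate early genes -0.33 (adjusted p = 0.0667). Without Ctrl replicate 2 the medians were type I interferon 0.23, ribosomal proteins -0.16, oxidative phosphorylation -0.14 and ER stress -0.093. With DPD replicate 1 left out they were cytotoxic effectors 0.63, ribosomal proteins -0.80, red blood cells -3.19, immediate early genes -0.46 and ER stress -0.40, and Hba-a1 stood at -3.17, Hbb-bs -3.39 and Cdkn1a -0.15. The medians without DPD replicate 2 were cytotoxic effectors 0.0915 (adjusted p = 0.184), ribosomal proteins -0.26, oxidative phosphorylation -0.22, red blood cells -0.96, immediate early genes -0.15 (adjusted p = 0.163) and ER stress -0.0859 (adjusted p = 0.189), and Gbp4 stood at 0.65, Oas3 0.53, Hba-a1 -0.93 and Hbb-bs -0.96. With a length trend (Spearman rho = 0.38) and GC trend removed the medians were ribosomal proteins -0.37, oxidative phosphorylation -0.30 and ER stress -0.14. The p53 list was at 0.0209 (camera adjusted p = 0.754) and Cdkn1a at -0.24 ± 0.20.

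In DPD against Ctrl 0 genes passed edgeR, 784 had an unadjusted p under 0.05 and DESeq2 called 7. The edgeR count was 1 without DPD replicate 1 and 1 without DPD replicate 2. Genes of smallest p were Pakap (5.54 ± 0.66), Apol10b (0.86 ± 0.18) and F13a1 (1.16 ± 0.25) on the higher side. On the lower side they were Pcdhgb2 (-1.63 ± 0.44), Ptprn (-0.82 ± 0.23) and Mmp9 (-0.98 ± 0.28), with edgeR adjusted p from 0.119 for Pakap to 0.725. Without Ctrl replicate 2 Pcdhgb2 stood at -0.95. In fits without DPD replicate 1 Mmp9 stood at -1.49. When DPD replicate 2 was left out Mmp9 stood at -0.60.

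The conjugate with DOX (R+X) had 0 lists above Ctrl and 5 below by camera at the preset correlation, and 0 with an estimated correlation (adjusted p from 0.591 to 0.865), while fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.225). Red blood cell genes fell (median -2.41; Hba-a1 -2.44 ± 0.59, Hbb-bs -2.45 ± 0.61), and 6 of 6 passed when adjusted over the list alone. Ribosomal (-0.53), oxidative phosphorylation (-0.43; Atp5o -0.73 ± 0.30), MHC class II (-0.47; Cd74 -0.59 ± 0.23, H2-Aa -0.65 ± 0.26, H2-Eb1 -0.71 ± 0.27) and ER stress genes (-0.28) fell as lists, with 0 members passing when adjusted over the list alone. Camera's adjusted p ran from 2.02e-07 to 0.0205. Leaving out Ctrl replicate 1 gave medians of ribosomal proteins -0.82 and ER stress -0.31 (adjusted p = 0.0528). Without Ctrl replicate 2 the medians were ribosomal proteins -0.21, oxidative phosphorylation -0.22 and ER stress -0.16, and Atp5o stood at -0.42. With R+X replicate 1 left out it was ER stress -0.26 (adjusted p = 0.0518), and Cdkn1a stood at -0.0471. With R+X replicate 2 left out Cdkn1a stood at -0.13. After removing a trend of length (Spearman rho = 0.46) and GC the medians were ribosomal proteins -0.34, oxidative phosphorylation -0.24 and ER stress -0.12. The count of 5 lists was 13 without Ctrl replicate 2 and 11 without R+X replicate 1. The interferon gamma list was at 0.30 (camera adjusted p = 0.086), T cells at -0.33 (adjusted p = 0.0897) and p53 targets at 0.0286 (adjusted p = 0.989). Cd274 stood at 0.35 ± 0.27, Prf1 at 0.72 ± 0.38, Mki67 at 0.67 ± 0.28 and Cdkn1a at -0.0839 ± 0.20.

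In R+X against Ctrl 0 genes passed edgeR, 1172 had an unadjusted p under 0.05 and DESeq2 called 4. Pakap (4.69 ± 0.64), Pygo1 (2.21 ± 0.41), Elk4 (2.33 ± 0.55), Saa3 (-2.82 ± 0.63), Hba-a1 and Hbb-bs were those of smallest p, with edgeR adjusted p from 0.405 to 0.575. Without Ctrl replicate 1 Saa3 stood at -1.69.

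By camera at its preset correlation, but not with an estimated correlation (adjusted p from 0.396 to 0.503), the conjugate with DPD (R+D) raised interferon gamma and lymphocyte lists over Ctrl, while fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.0674). All 26 interferon gamma genes were positive (median 0.98; Gbp2 1.25 ± 0.24, Gbp4 1.65 ± 0.36, Ido1 2.27 ± 0.47, Serpina3g 1.01 ± 0.16), and 21 passed when adjusted over the list alone. Cytotoxic effectors (median 0.92; Prf1 1.501 ± 0.38, Gzmb 1.304 ± 0.38) rose with 3 of 21 passing that way. T cell (0.76; Cd3g 1.301 ± 0.39, Cd27 1.42 ± 0.39), regulatory T cell (1.05; Foxp3 1.09 ± 0.48, Tnfrsf18 1.25 ± 0.41) and checkpoint lists (0.58) rose with 0 members passing. At the preset correlation, the adjusted p of camera was 8.34e-12 for interferon gamma, 2.12e-06 for cytotoxic effectors and 0.000328 for T cells, and the adjusted p = 0.402, 0.427 and 0.427 with an estimated correlation. The regulatory T cell and checkpoint lists had camera adjusted p = 0.0198, or adjusted p = 0.427 with an estimated correlation. R+D replicate 2 is the library rich in muscle transcripts. The muscle list itself rose (median 2.83; Tnnc2 2.65 ± 0.70, Ryr1 2.41 ± 0.61; 18 of 20 passing when adjusted over the list alone; camera adjusted p = 5.52e-06, or adjusted p = 0.427 with an estimated correlation). The medians without Ctrl replicate 1 were regulatory T cells 0.95 (adjusted p = 0.0604) and checkpoints 0.90. Leaving out Ctrl replicate 2 gave a median of checkpoints 0.32 (adjusted p = 0.13). In fits without R+D replicate 1 Ido1 stood at 1.48 and Foxp3 0.69. Without R+D replicate 2 the medians were cytotoxic effectors 0.29, T cells 0.33 (adjusted p = 0.0794), regulatory T cells 0.69 (adjusted p = 0.0638), checkpoints 0.17 (adjusted p = 0.252) and muscle 0.21 (adjusted p = 0.112), and Prf1 stood at 0.94, Gzmb 0.85, Tnnc2 0.81 and Ryr1 1.07. The fit with the muscle covariate gave cytotoxic effectors 0.37, T cells 0.26 (adjusted p = 0.574), regulatory T cells 0.59 (adjusted p = 0.201), checkpoints 0.13 (adjusted p = 0.458) and muscle -0.25 (adjusted p = 0.75), and Cd3g stood at 0.68, Tnnc2 0.49 and Ryr1 0.84.

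Lower in R+D than in Ctrl were red blood cell genes (median -3.14; Hba-a1 -3.17 ± 0.60), ribosomal (-0.67; Rps14 -1.12 ± 0.36), oxidative phosphorylation (-0.56) and MHC class II genes (-0.57; Cd74 -0.77 ± 0.23, H2-Eb1 -1.01 ± 0.28). So were ER stress (-0.40; Atf3 -0.93 ± 0.25, Herpud1 -0.53 ± 0.16, Xbp1 -0.62 ± 0.20), NRF2 (-0.23; Nqo1 -0.92 ± 0.22, Sqstm1 -0.79 ± 0.20), immediate early (-0.20; Hspa1b -0.96 ± 0.30) and hypoxia lists (-0.29; Bnip3 -0.71 ± 0.28, Eno1 -0.50 ± 0.20, but Pfkfb3 0.70 ± 0.26). When adjusted over the list alone, 5 of 6 red blood cell, 3 of 11 MHC class II and 3 of 20 NRF2 genes passed, and 0 in the other 5 lists. Camera's adjusted p ran from 6.08e-08 for ribosomal proteins to 0.0218 for hypoxia, and from adjusted p = 0.396 to 0.503 with an estimated correlation. With Ctrl replicate 2 left out they were ribosomal proteins -0.31, oxidative phosphorylation -0.31 and hypoxia -0.20 (adjusted p = 0.0749), and Rps14 stood at -0.52 and Bnip3 -0.25. When R+D replicate 1 was left out Bnip3 stood at -0.42. The median without R+D replicate 2 was immediate early genes -0.22 (adjusted p = 0.0844), and Bnip3 stood at -1.13. Medians with the muscle covariate were MHC class II -0.90 and immediate early genes -0.29 (adjusted p = 0.19). With the trend of length (Spearman rho = 0.35) and GC removed the medians were ribosomal proteins -0.49, oxidative phosphorylation -0.42 and ER stress -0.26. The p53 list was at 0.0241 (camera adjusted p = 0.79), Cdkn1a at -0.39 ± 0.20, Cd274 at 0.74 ± 0.27 and Mki67 at 1.12 ± 0.28.

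In R+D against Ctrl 0 genes passed edgeR, 2998 had an unadjusted p under 0.05 and DESeq2 called 232. The edgeR count was 1 without R+D replicate 1, and in fits added later it was 5 without DPD replicate 1 and 5 without DPD replicate 2. Pakap (5.39 ± 0.66), Apol10b (1.31 ± 0.18) and Gja4 (1.81 ± 0.27) had the smallest p on the higher side. Hbb-bt (-3.15 ± 0.60), Hba-a1 and Ociad2 (-0.93 ± 0.18) had it on the lower side, with edgeR adjusted p from 0.145 to 0.314.

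**Figure D4:**
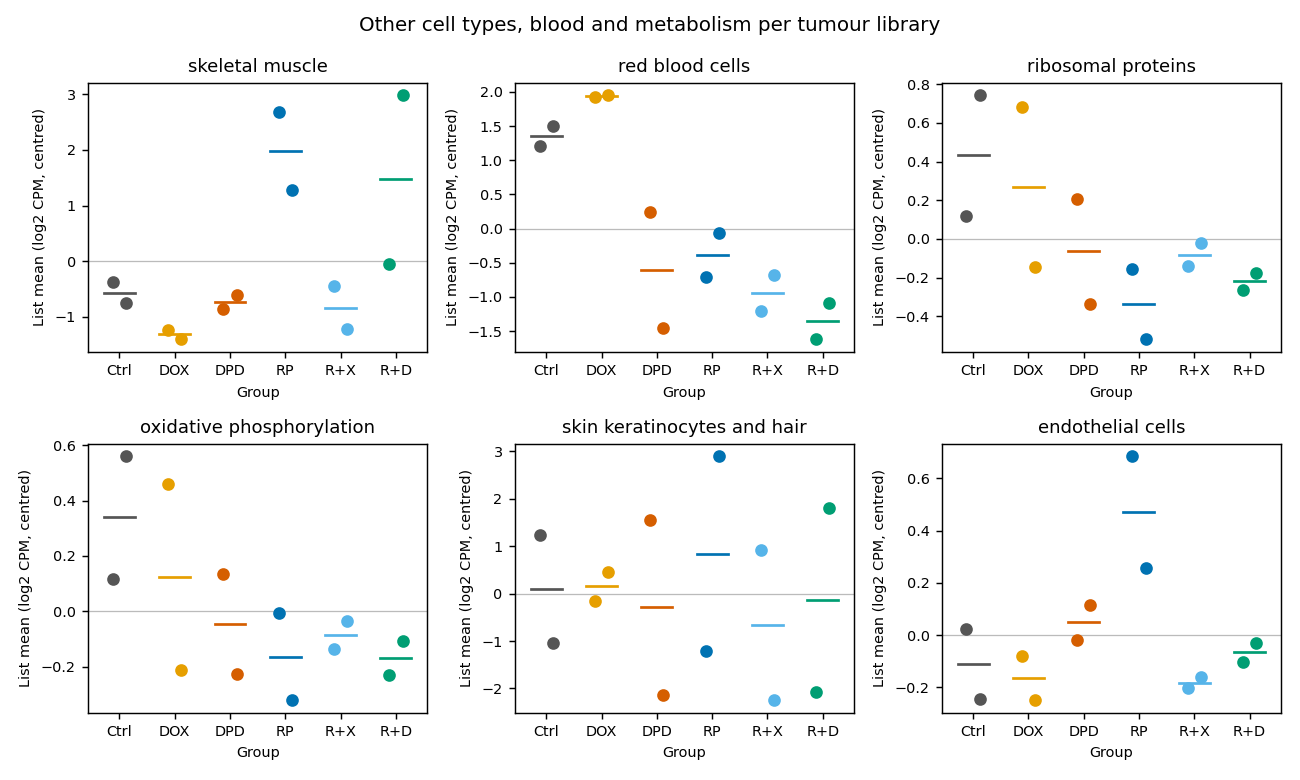
Mean log2 CPM of 6 lists of other tissues, blood and metabolism in each library, centred on the mean of the 12 libraries, by group; points are libraries and lines group means, and each panel has its own range. For skeletal muscle RP replicate 1 sat at 2.68, RP replicate 2 at 1.28 and R+D replicate 2 at 2.98, against -0.0454 in R+D replicate 1 and -0.37 in Ctrl replicate 1.

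DPD and DOX, given alone at the same dose of 14 µg and by the same route, were compared directly. Immune lists were higher with DPD by camera at the preset correlation, but 0 lists passed with an estimated correlation (smallest adjusted p = 0.237), and fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.139). The interferon gamma response was higher in 26 of 26 genes (median 0.78; Serpina3g 0.80 ± 0.16, Ciita 1.01 ± 0.24, Gbp4 1.31 ± 0.36, Cxcl9 1.07 ± 0.35), of which 16 passed when adjusted over the list alone. T cell genes were higher in 21 of 21 (median 0.85; Cd3e 1.27 ± 0.36, Zap70 0.97 ± 0.32), and cytotoxic effectors (0.53; Klrk1 1.43 ± 0.31, Ccl5 0.80 ± 0.31) in 20 of 21, with 0 and 1 passing that way. By list mean per library the difference of DPD and DOX was 0.83 (95% interval 0.23 to 1.42) for interferon gamma, 0.82 (95% interval 0.0145 to 1.62) for T cells and 0.67 (95% interval -0.0246 to 1.37) for cytotoxic effectors, with limma adjusted p = 0.23, 0.257 and 0.257. At the preset correlation, the adjusted p of camera was 1.02e-18, 8.24e-11 and 2.2e-06, and for each the adjusted p = 0.345 with an estimated correlation. The interferon gamma interval included 0 without DOX replicate 1 (0.63 (-0.11 to 1.36)) or DPD replicate 2 (0.66 (-0.11 to 1.42)), and the T cell interval whichever of the 4 libraries was left out, as for DPD replicate 2 (0.63 (-0.44 to 1.70)). Red blood cell genes were lower with DPD (median -2.22; Hbb-bt -2.57 ± 0.58; 6 of 6 passing when adjusted over the list alone; camera adjusted p = 1.08e-11, or adjusted p = 0.237 with an estimated correlation). Leaving out DOX replicate 1 gave a median of cytotoxic effectors 0.95. Without DOX replicate 2 the median was cytotoxic effectors 0.50 (adjusted p = 0.0666). With DPD replicate 1 left out they were cytotoxic effectors 0.81 and red blood cells -3.74, and Hbb-bt stood at -4.10. The median without DPD replicate 2 was T cells 0.54, and Gbp4 stood at 0.86. The p53 list did not separate the compounds, with a difference of list means of -0.00218 (95% interval -0.35 to 0.34) and a camera adjusted p = 0.93.

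Camera called 18 lists between DPD and DOX, 13 higher and 5 lower with DPD, and the 14 besides those above were each lost when some single library was left out. With all libraries the medians were MHC class I 0.25, MHC class II 0.56, macrophages 0.30, dendritic cells 0.50, checkpoints 0.49, regulatory T cells 0.79, B cells 1.25, type I interferon 0.19, cell cycle 0.10, endothelial cells 0.15, ribosomal proteins -0.35, oxidative phosphorylation -0.25, hypoxia -0.25 and immediate early genes -0.25. Leaving out DOX replicate 1 gave medians of MHC class I 0.63, macrophages 0.48, checkpoints 0.53 (adjusted p = 0.0979), regulatory T cells 0.58 (adjusted p = 0.261), B cells 0.74 (adjusted p = 0.0904), type I interferon 0.0897 (adjusted p = 0.339), cell cycle 0.0887 (adjusted p = 0.0963), endothelial cells 0.30, ribosomal proteins 0.13 (adjusted p = 0.699), oxidative phosphorylation 0.15 (adjusted p = 0.186), hypoxia 0.0336 (adjusted p = 0.851) and immediate early genes -0.0456 (adjusted p = 0.851), and Cd274 stood at 0.38. Without DOX replicate 2 the medians were MHC class I -0.0753 (adjusted p = 0.844), MHC class II 0.33 (adjusted p = 0.373), macrophages 0.0166 (adjusted p = 0.185), dendritic cells 0.34 (adjusted p = 0.221), B cells 0.75 (adjusted p = 0.356), type I interferon 0.58, cell cycle 0.0614 (adjusted p = 0.282), endothelial cells 0.11 (adjusted p = 0.683), ribosomal proteins -0.70, oxidative phosphorylation -0.45 and immediate early genes -0.43, and Lyz2 stood at 0.32 and Cd274 1.16. With DPD replicate 1 left out they were macrophages 0.11 (adjusted p = 0.0814), regulatory T cells 1.32, cell cycle 0.11 (adjusted p = 0.0926), endothelial cells 0.24 (adjusted p = 0.0733), ribosomal proteins -0.65, oxidative phosphorylation -0.42 and hypoxia -0.25 (adjusted p = 0.453). The medians without DPD replicate 2 were regulatory T cells 0.0535 (adjusted p = 0.444), B cells 0.55 (adjusted p = 0.167), cell cycle 0.0651 (adjusted p = 0.14), endothelial cells 0.11 (adjusted p = 0.261), ribosomal proteins -0.13 (adjusted p = 0.389), oxidative phosphorylation -0.0496 (adjusted p = 0.999) and immediate early genes -0.0594 (adjusted p = 0.344). With the muscle score as a covariate the medians were type I interferon 0.30, cell cycle 0.10 (adjusted p = 0.059) and endothelial cells 0.10 (adjusted p = 0.116). With the skin covariate cell cycle (0.10, adjusted p = 0.054), B cells (1.27, adjusted p = 0.0693) and endothelial cells (0.14, adjusted p = 0.0661) were not called. The count was 9 without DOX replicate 1 and 10 without DOX replicate 2. Adjusted p ran from 0.237 to 0.641 with an estimated correlation over the 18 lists. Members of these lists included Cd74 (0.53 ± 0.23), Ctss (0.62 ± 0.19), Lyz2 (0.48 ± 0.16), Fcgr3 (0.53 ± 0.16) and P4ha1 (-0.37 ± 0.14). The edgeR count was 0 (1 without DOX replicate 2), 837 had an unadjusted p under 0.05 and DESeq2 called 9. Of smallest p were Apol10b (1.21 ± 0.18), Apol6 (1.54 ± 0.29), Serpina3f (1.68 ± 0.33), Kdm5b (-0.82 ± 0.17), Medag (-0.83 ± 0.19) and Hbb-bt. Cxcl10 stood at 0.78 ± 0.24 and Cd274 at 0.72 ± 0.27.

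The same pair of compounds was compared in the presence of the conjugate, as R+D against R+X. Camera called 10 lists at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.271), and fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.161). All 26 interferon gamma genes were higher in R+D (median 0.80; Serpina3g 0.80 ± 0.16, Cxcl10 0.96 ± 0.24, Gbp2 0.92 ± 0.24), and 13 passed when adjusted over the list alone. T cell genes were higher in 21 of 21 (median 1.10; Cd3g 1.39 ± 0.39, Cd8b1 1.33 ± 0.38, Cd8a 1.09 ± 0.44, Zap70 1.10 ± 0.31), and cytotoxic effectors in 20 of 21 (median 0.97; Ccl5 1.14 ± 0.31, Nkg7 1.29 ± 0.38, Gzmb 1.19 ± 0.38), with 3 and 3 passing that way. Hypoxia (median -0.31; Ndrg1 -0.66 ± 0.16, Slc2a1 -0.89 ± 0.23) and NRF2 genes (-0.14; Nqo1 -0.66 ± 0.22, Sqstm1 -0.51 ± 0.20) were lower, with 2 and 0 passing. By list mean the difference of R+D and R+X was 0.72 (95% interval 0.13 to 1.32) for interferon gamma, 0.97 (95% interval 0.17 to 1.77) for T cells, 0.96 (95% interval 0.26 to 1.66) for cytotoxic effectors and -0.38 (95% interval -0.68 to -0.0715) for hypoxia, each with a limma adjusted p = 0.161. These differences leaned on single libraries: without R+X replicate 2 they were 0.47 (-0.20 to 1.14) for interferon gamma and 0.58 (-0.24 to 1.41) for T cells, and without R+D replicate 2 0.62 (-0.0921 to 1.33) for cytotoxic effectors. Each of these 3 intervals included 0 without R+X replicate 2 and without R+D replicate 2, and that of interferon gamma also without R+D replicate 1. The hypoxia interval included 0 whichever of the 4 libraries was left out, as for R+D replicate 1 (-0.34 (-0.76 to 0.0842)). Camera's adjusted p was 8.38e-15 for interferon gamma, 1.84e-13 for T cells, 7.26e-12 for cytotoxic effectors, 3.29e-08 for hypoxia and 0.00396 for NRF2. With an estimated correlation the adjusted p = 0.271 for the first 3 and NRF2 and adjusted p = 0.272 for hypoxia. Muscle genes were higher in R+D, through R+D replicate 2 (list mean 2.98) more than R+D replicate 1 (-0.0454), against -0.45 and -1.22 in R+X (median 2.87; Tnnc2 2.74 ± 0.70; 18 of 20 passing when adjusted over the list alone; camera adjusted p = 1.84e-13, or adjusted p = 0.371 with an estimated correlation). Leaving out R+X replicate 1 gave a median of NRF2 -0.25, and Cd8b1 stood at 2.00 and Cd8a 1.76. With R+X replicate 2 left out Cd8b1 stood at 0.84 and Cd8a 0.60. Without R+D replicate 2 the medians were T cells 0.52, cytotoxic effectors 0.33 and muscle 0.76, and Cd8a stood at 0.59, Ccl5 0.59, Nkg7 0.51, Gzmb 0.73 and Tnnc2 0.90. The fit with the muscle covariate gave T cells 0.37, cytotoxic effectors 0.29 and muscle 0.0283 (adjusted p = 0.909), and Cd3g stood at 0.70, Cd8b1 0.73, Cd8a 0.49, Zap70 0.54, Ccl5 0.36, Nkg7 0.32, Gzmb 0.76 and Tnnc2 0.31.

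Weaker calls between R+D and R+X were those of regulatory T cells (0.76), inflammatory cytokines (0.36), MHC class I (0.28) and B cells (0.55), with camera adjusted p from 0.00451 to 0.0388 and from adjusted p = 0.387 to 0.762 with an estimated correlation. With R+X replicate 2 left out they were inflammatory cytokines 0.23 (adjusted p = 0.362), MHC class I 0.17 (adjusted p = 0.423) and B cells 0.37 (adjusted p = 0.323), and Chil3 stood at -1.71. The median without R+D replicate 1 was B cells 0.85. Leaving out R+D replicate 2 gave medians of regulatory T cells 0.50, inflammatory cytokines 0.0506 (adjusted p = 0.667), MHC class I 0.10 (adjusted p = 0.672) and B cells 0.25 (adjusted p = 0.424). Medians with the muscle covariate were regulatory T cells 0.37 (adjusted p = 0.256), inflammatory cytokines 0.0742 (adjusted p = 0.416), MHC class I 0.00696 (adjusted p = 0.519) and B cells 0.23 (adjusted p = 0.909). The count of 10 lists was 18 without R+X replicate 1. In edgeR 0 genes passed (1 without R+D replicate 1), 1028 had an unadjusted p under 0.05 and DESeq2 called 42. Gja4 (1.62 ± 0.27), Apol10b (0.98 ± 0.18), Zbp1 (0.88 ± 0.17), Chil3 (-2.77 ± 0.54), Lrch4 (-1.15 ± 0.26) and Mex3b (-0.74 ± 0.17) had the smallest p. Cd274 stood at 0.39 ± 0.27, and p53 targets at -0.0182 (camera adjusted p = 0.625).

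Against RP, each combination also added the injection beside the tumour. R+X against RP had lower interferon gamma (median -1.22), T cell (-1.39) and cytotoxic genes (-1.43). Of these, 24 of 26, 18 of 21 and 15 of 21 passed when adjusted over the list alone. Their camera adjusted p was 2.53e-23, 7.17e-17 and 1.61e-15, and the adjusted p = 0.149 for each with an estimated correlation. Muscle genes were lower as well (-2.93; camera adjusted p = 6.28e-14, or adjusted p = 0.167 with an estimated correlation). Without RP replicate 1 the median was muscle -1.89. With R+X replicate 1 left out it was T cells -2.14. Without R+X replicate 2 H1f2 stood at 0.74. With the muscle score as a covariate the medians were T cells -0.67, cytotoxic effectors -0.76 and muscle -0.10 (adjusted p = 0.933), and H1f2 stood at 0.81. Of 22 lists called, 3 were higher, and 13 were called with that covariate, while fry called 5 lists and the list means 0 (smallest limma adjusted p = 0.0519). Plac8 (-2.11 ± 0.26), Serpina3g (-1.23 ± 0.16) and Gja4 (-2.11 ± 0.28) each had an edgeR adjusted p = 0.0609, with Nr2f1 (0.82 ± 0.19) and H1f2 (1.25 ± 0.29) on the higher side. No gene passed edgeR (7 without RP replicate 2), 1694 had an unadjusted p under 0.05 and DESeq2 called 305.

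R+D was then compared with RP. Endothelial (-0.59), neutrophil (-0.90), interferon gamma (-0.42) and macrophage lists (-0.39) were among 19 that were lower, with camera adjusted p from 1.03e-12 to 7.87e-08 and from adjusted p = 0.14 to 0.268 with an estimated correlation. The count was 8 without R+D replicate 1, and fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.251). T cells (-0.51, camera adjusted p = 0.000236, or adjusted p = 0.373 with an estimated correlation) were lower too. The medians without RP replicate 1 were endothelial cells -0.33 and T cells -0.22. Leaving out RP replicate 2 gave a median of interferon gamma -0.28. Without R+D replicate 1 the medians were macrophages -0.25 and T cells -0.0789 (adjusted p = 0.449). The neutrophil median was -0.81 with the skin covariate. In edgeR 0 genes passed (1 without R+D replicate 1), 534 had an unadjusted p under 0.05 and DESeq2 called 10. Slc11a1 (-0.93 ± 0.17), Plac8 (-1.27 ± 0.25), Ms4a4d (-1.54 ± 0.33), Guca1b (1.56 ± 0.34) and Adam1a (1.22 ± 0.28) had small unadjusted p.

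What the conjugate added to each drug was confounded with the route of the drug. R+D was above DPD for muscle (3.09), interferon gamma (0.39), cytotoxic (0.70) and T cell genes (0.44), and below it for type I interferon (-0.46) and MHC class II genes (-0.46). At the preset correlation, the adjusted p of camera ran from 3.47e-16 for muscle to 0.000988 for T cells, and from adjusted p = 0.441 to 0.586 with an estimated correlation, while fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.763). With DPD replicate 1 left out they were interferon gamma 0.22 (adjusted p = 0.0967), cytotoxic effectors 0.34 (adjusted p = 0.104) and T cells 0.32 (adjusted p = 0.194). The median without R+D replicate 1 was T cells 0.80. Leaving out R+D replicate 2 gave medians of muscle 0.69, interferon gamma 0.19, cytotoxic effectors 0.0923 (adjusted p = 0.499), T cells 0.0256 (adjusted p = 0.777) and type I interferon -0.18 (adjusted p = 0.141), and Casq1 stood at 1.61. The fit with the muscle covariate gave muscle 0.0602 (adjusted p = 0.821), interferon gamma 0.21, cytotoxic effectors 0.12 (adjusted p = 0.951), T cells -0.0605 (adjusted p = 0.0682), type I interferon -0.17 and MHC class II -0.77, and Casq1 stood at 0.91. The count of 13 lists was 6 without DPD replicate 1. The edgeR count was 0 (1 without R+D replicate 1), 450 had an unadjusted p under 0.05 and DESeq2 called 7; Gja4 was at 1.23 ± 0.27, Casq1, a muscle gene, at 3.82 ± 0.93, Hp at -1.24 ± 0.30 and Slc11a1 at -0.67 ± 0.17. R+X against DOX had lower red blood cell genes (-2.94; Hba-a1 -2.97 ± 0.60, Alas2 -2.45 ± 0.49; 6 of 6 passing when adjusted over the list alone) with a camera adjusted p = 5.84e-14, or adjusted p = 0.148 with an estimated correlation. Its interferon gamma genes were higher (0.38; camera adjusted p = 2.12e-06, or adjusted p = 0.76 with an estimated correlation). Without DOX replicate 1 the median was interferon gamma 0.18. With DOX replicate 2 left out it was interferon gamma 0.65. The median without R+X replicate 1 was interferon gamma 0.12 (adjusted p = 0.117), and Apol6 stood at 0.68. Leaving out R+X replicate 2 gave a median of interferon gamma 0.61, and Chil3 stood at 1.05 and Irf4 1.09. Camera called 7 lists, 11 without DOX replicate 1 and 4 without DOX replicate 2, and fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.076). In edgeR 0 genes passed (1 without DOX replicate 2), 546 had an unadjusted p under 0.05 and DESeq2 called 3; Apol6 was at 1.20 ± 0.28, Chil3 at 2.14 ± 0.53 and Irf4 at 1.67 ± 0.43.

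Averaged over no drug, DOX and DPD, the conjugate came with a changed route of either drug. Gja4 rose by 1.41 ± 0.16, Apol10b by 0.94 ± 0.10 and Serpina3g by 0.81 ± 0.0912 log2 units. Each had an edgeR adjusted p = 0.021, with 6 libraries per side. Of the interferon gamma genes, 25 of 26 passed when adjusted over the list alone (median 0.75), and the list mean rose by 0.75 (95% interval 0.40 to 1.09) with a limma adjusted p = 0.0189. Red blood cell genes fell (median -2.02; Hba-a1 -2.1 ± 0.33, Hbb-bs -2.11 ± 0.35), with a change of the list mean of -1.79 (95% interval -2.60 to -0.98), with a limma adjusted p = 0.0189. Cytotoxic (0.66) and T cell genes (0.65) rose, as did muscle genes (2.105; camera adjusted p = 2.23e-08), and ribosomal protein genes (-0.43) fell. Camera's adjusted p was 1.08e-14 for interferon gamma, 8.32e-08 for red blood cells, 1.48e-07 for cytotoxic effectors, 4.84e-06 for T cells and 8.32e-09 for ribosomal proteins, and from adjusted p = 0.342 to 0.441 with an estimated correlation. Without R+D replicate 2 the medians were T cells 0.36 and muscle 1.299. Medians with the muscle covariate were cytotoxic effectors 0.37, T cells 0.16 (adjusted p = 0.639) and muscle -0.0374 (adjusted p = 0.897). After removing the length (Spearman rho = 0.34) and GC trend the ribosomal median was -0.31. Beside camera's 13 lists, fry called 7 lists and the list means 4 (smallest limma adjusted p = 0.0189). Nr2f1 was at -0.66 ± 0.11. With 3968 genes at an unadjusted p under 0.05 and 951 called by DESeq2, edgeR passed 3, and 0 in an additive fit or with the muscle score as a covariate. The count depended on single libraries: it was 3233 without DOX replicate 2, 37 without DPD replicate 2, 6 without R+D replicate 1 and 5 without DOX replicate 1. It was 0 without Ctrl replicate 1, Ctrl replicate 2, DPD replicate 1, RP replicate 1, RP replicate 2, R+X replicate 1 or R+D replicate 2.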

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

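Predictions for the length and GC, muscle and library split tests were written before those tests were run, while the tests on host cells, on Ctrl replicate 2 and on the split of the interferon gamma median were chosen after the result was seen. The muscle and skin covariates were too.

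Only camera at its preset correlation called lists whose drug effect, tested as a difference, changed with the conjugate, and the drug's route changed too. With DPD, 17 lists differed (4 higher, 13 lower), led by the interferon gamma response (median -1.03), endothelial cells (-0.76), ribosomal proteins (0.63) and the type I interferon response (-0.55), with camera adjusted p from 5.94e-15 to 1.12e-06 and from adjusted p = 0.378 to 0.499 with an estimated correlation. The count was 11 without R+D replicate 1, and fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.354). With Ctrl replicate 2 left out it was ribosomal proteins 0.27. The median without DPD replicate 1 was ribosomal proteins 0.95. Leaving out DPD replicate 2 gave a median of ribosomal proteins 0.39. Without RP replicate 1 the median was type I interferon -0.30. With RP replicate 2 left out it was ribosomal proteins 0.42. The median without R+D replicate 1 was type I interferon -0.89. Leaving out R+D replicate 2 gave a median of type I interferon -0.35. With DOX, 18 lists differed (4 higher, 14 lower), led by interferon gamma (-1.03), cytotoxic effectors (-1.20), inflammatory cytokines (-0.94) and skeletal muscle (-2.22), with camera adjusted p from 2.16e-14 to 7.21e-07 and from adjusted p = 0.333 to 0.418 with an estimated correlation. The count was 9 without DOX replicate 2 and 11 without Ctrl replicate 2, and fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.381). Without RP replicate 1 the median was muscle -1.39. In fits without R+X replicate 2 Chil3 stood at 1.88. With the muscle score as a covariate the medians were cytotoxic effectors -0.76 and muscle 0.14 (adjusted p = 0.947). In edgeR 0 genes passed in either test, and DESeq2 called 11 (DPD) and 6 (DOX). At an unadjusted p under 0.05 were 871 (DPD) and 724 (DOX) genes, fewer than the 976 of chance. Values of small p were F13a1 (-1.96 ± 0.35), Slfn4 (-3.72 ± 0.67), Egr3 (1.13 ± 0.28) and Pakap (-4.62 ± 0.81) for DPD. For DOX they were Plac8 (-2.19 ± 0.36), Zbp1 (-1.32 ± 0.24), Chil3 (2.95 ± 0.73) and Pakap (-4.69 ± 0.82).

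By camera at its preset correlation, but by no other list test, the gap between DPD and DOX changed with the conjugate for 5 lists. These were red blood cells (median 1.49), skeletal muscle (2.44), MHC class II (-0.71), macrophages (-0.30) and inflammatory cytokines (0.37), with camera adjusted p from 4.24e-07 to 0.0314 and from adjusted p = 0.645 to 0.891 with an estimated correlation. With DOX replicate 1 left out it was macrophages -0.48. The medians without DOX replicate 2 were MHC class II -0.47 (adjusted p = 0.214), macrophages -0.21 (adjusted p = 0.214) and inflammatory cytokines 0.10 (adjusted p = 0.56). Leaving out DPD replicate 1 gave medians of red blood cells 3.05, macrophages -0.0653 (adjusted p = 0.168) and inflammatory cytokines 0.38 (adjusted p = 0.168). Without DPD replicate 2 the median was red blood cells 0.76. With R+X replicate 2 left out they were macrophages -0.13 and inflammatory cytokines 0.30 (adjusted p = 0.399), and Chil3 stood at -2.11. The median without R+D replicate 1 was macrophages -0.18 (adjusted p = 0.0711). Leaving out R+D replicate 2 gave medians of muscle 0.24 (adjusted p = 0.354) and inflammatory cytokines 0.0643 (adjusted p = 0.476), and Mylpf stood at 3.14. The fit with the muscle covariate gave muscle 0.18 (adjusted p = 0.645) and inflammatory cytokines 0.11 (adjusted p = 0.265), and Mylpf stood at 2.83. With the skin covariate the inflammatory median was 0.14 (adjusted p = 0.086). The count was 8 without DOX replicate 1, 10 without R+X replicate 1 and 8 without R+D replicate 1, and fry called 0 lists and the list means 0 (smallest limma adjusted p = 0.981). The edgeR count was 0, DESeq2 called 3, and 413 genes had an unadjusted p under 0.05, fewer than the 976 of chance. Chil3 was at -3.18 ± 0.74, Itgb2 at -0.97 ± 0.23 and Mylpf, a muscle gene, at 5.52 ± 1.46.

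A first pattern to weigh is the higher immune lists in RP and R+D. With more host cells of every kind, T cell markers would rise no more than macrophage, fibroblast and endothelial ones. Their median lay 1.03 log2 above (bootstrap interval over genes 0.55 to 1.24) in RP and 0.87 (0.69 to 1.14) in R+D. Without R+D replicate 2 the R+D value was 0.44 (0.27 to 0.91) and the T cell list lost its call (0.33). With the muscle covariate the values were 0.14 (-0.14 to 1.005) in RP and 0.46 (0.0608 to 0.80) in R+D. Neutrophils (1.05 in RP), B cells (0.98) and dendritic cells (0.85) were not compared, and intervals are over genes only. So more host cells were not excluded in either group, least of all in RP with that covariate. A length and GC trend is argued against by interferon gamma medians of 1.505 in RP and 1.03 in R+D after that trend was removed. Muscle carried into the sample is argued against for the interferon gamma list only, with medians of 1.44 and 0.92 when the muscle score was a covariate, while T cell medians fell to 0.23 in RP and 0.26 in R+D, and MHC class I and B cells in RP to -0.00839 and -0.33, so for those lists it stays open. An effect of the conjugate on immune cells or their signalling stays open as a hypothesis, and so do differences between tumours in size or sampled region, which were not measured here.

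The muscle transcripts of RP replicate 1, RP replicate 2 and R+D replicate 2 are a second pattern. In each, 95% of the muscle list lay above the highest Ctrl library, and adult fast myosins rose by 57.4, 13.4 and 72 CPM over Ctrl against 4.65, 0.291 and 2.02 for embryonic ones. Adult skeletal muscle taken with the tumour is thus a candidate source. Whether the tumours had grown into muscle or were cut differently was not tested.

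The last pattern is the lower ribosomal protein and oxidative phosphorylation lists with the conjugate. DPD alone had lower ribosomal genes too, against the same Ctrl libraries (-0.51, and -0.37 after a length and GC trend was removed, against -0.53 and -0.34 in R+X). A length and GC trend is argued against as the whole cause, since for the conjugate averaged over drugs the medians were -0.31 and -0.21 after removing it, from -0.43 and -0.33. Ctrl replicate 2, which had the highest ribosomal share, is argued against as the only cause, since without it the medians for RP against Ctrl were -0.44 and -0.29, from -0.82 and -0.57. The difference may in part come from both. Against Ctrl, fold changes rose with transcript length (Spearman rho from 0.34 in RP to 0.46 in R+X), but these comparisons share the Ctrl libraries, and rho was 0.16 for DPD against DOX and -0.0353 for R+D against R+X. RNA quality was not measured here.

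Chance was asked by regrouping the libraries within each drug setting, with 100 of 108 splits drawn. For the conjugate averaged over drugs, 4 of 100 splits gave at least the 3 genes of the real split, fewer than 5 in 100, although another split gave 13. That split exchanged DPD replicate 2 with R+D replicate 1. More genes than in the real split may point to a structure of the samples or to an unstable count, and these were not separated. For lists, 28 of 100 splits gave at least the real 13 (highest other 22), so chance is not excluded. The interferon gamma median, 0.75, was reached by 1 of 100 splits, the real one, with 0.74 as the highest other value.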

How the results depend on the processing

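No paired analysis was possible because the labels give no shared replicate numbers. With 2 libraries per group, counts of single genes differed between tools and fits and with the library left out, most for the averaged conjugate without DOX replicate 2 (3233); edgeR's shared spread has 6 residual degrees of freedom. Also chosen after seeing the data were list means with 1 library left out and all host cell tests. Over 3091 values of 209 gene results followed, 2845 kept direction and side of the threshold, 184 passed it anew, 59 no longer did and 3 turned. Over 2010 values of 194 called list medians, 1352 did so, 627 lost the call and 31 turned. Of the gene results, only those of 3 genes for RP against Ctrl and 3 averaged passed at the start. All 59 losses came from these calls, and the 2845 values mostly belong to results that had no call to lose. For genes, a missing adjusted p counted as the same side. RLE scaling gave 2 genes for RP against Ctrl in place of 3, with Gja4 at an adjusted p = 0.0512 in edgeR, and summed name copies gave 4. Unless stated, the cause of a move was not tested.

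Genes called, in the order DOX, DPD, RP, R+X and R+D against Ctrl, were 1, 7, 1211, 4 and 232 in DESeq2, against 0, 0, 3, 0 and 0. DESeq2 called 9 for DPD against DOX, 42 for R+D against R+X, 10 for R+D against RP, 7 for R+D against DPD, 305 for R+X against RP and 3 for R+X against DOX. It called 11 and 6 for the differences by DPD and DOX, 3 for the difference between those, and 951 for the averaged conjugate. Without the low-count filter the counts were 1 for DOX, 1 for DPD, 14 for RP, 1 for R+D, 5 for R+X against RP and 13 averaged. With the 2 compared groups alone they were 2 for DOX, 505 for RP, 6 for R+X, 8 for R+D, 1 for DPD against DOX, 1 for R+D against RP, 3 for R+D against DPD and 1 for R+X against RP. Limma-voom gave 16 for RP and 5 for R+X against RP, the additive fit gave 0 averaged, both DOX libraries left out gave 36 for RP, and the muscle covariate gave 0 for RP and 0 averaged. With an estimated correlation 0 lists were called in every comparison, and by list means 0, except 8 for RP and 4 averaged; the muscle covariate gave 11 lists for RP and 13 for R+X against RP.

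Leaving out 1 library gave genes from 0 to 1 for DOX, DPD, R+D against R+X, R+D against RP, R+D against DPD, DPD against DOX, R+X against DOX, both drug differences and the difference between them. The range was 0 to 48 for RP, 0 to 0 for R+X, 0 to 5 for R+D, 0 to 7 for R+X against RP and 0 to 3233 averaged. Lists ranged from 4 to 9 for DOX, 8 to 12 for DPD, 14 to 18 for RP, 5 to 13 for R+X, 11 to 19 for R+D, 9 to 15 for DPD against DOX and 7 to 18 for R+D against R+X. They ranged from 8 to 20 for R+D against RP, 6 to 15 for R+D against DPD, 18 to 22 for R+X against RP, 4 to 11 for R+X against DOX, 11 to 21 and 9 to 19 for the differences by DPD and DOX, 5 to 10 between those and 12 to 18 averaged.

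Signs turned in these cases, given with the other end of the range where 1 library was left out. For DOX against Ctrl, interferon gamma was 0.0613 without Ctrl replicate 1, 0.0761 without DOX replicate 1 and -0.37 without DOX replicate 2. Oxidative phosphorylation was 0.0656 without Ctrl replicate 2. Without DOX replicates 1 and 2 in turn, oxidative phosphorylation was -0.53 and 0.0742, MHC class I -0.65 and 0.0431, Cdkn1a -0.55 and 0.12, Top2a 0.33 and -0.13, and Cd274 0.25 and -0.54. In the same order, DPD against DOX gave hypoxia 0.0336 and -0.37, oxidative phosphorylation 0.15 and -0.45, ribosomal proteins 0.13 and -0.70, immediate early genes -0.0456 (turned by the test's direction) and -0.43, and MHC class I 0.63 and -0.0753. R+X against DOX gave oxidative phosphorylation 0.0873 and -0.49 and ribosomal proteins 0.053 and -0.78. Without DPD replicates 1 and 2 in turn, R+D against DPD gave oxidative phosphorylation 0.0611 and -0.32, red blood cells 0.14 and -2.23, and ribosomal proteins 0.10 and -0.40, and the red blood cell difference by DPD was 1.89 and -0.36. Without RP replicates 1 and 2 in turn, R+D against RP gave MHC class II 0.0545 and -0.85 and adipocytes 0.24 and -1.66, and R+X against RP gave adipocytes 0.15 and -1.63. Skin in R+X against RP was 1.73 without RP replicate 2 and -5.82 without R+X replicate 1. Type I interferon in R+D against RP was -0.53 without R+D replicate 1 and -0.0197, turned by direction, without R+D replicate 2. With the muscle score as a covariate, RP against Ctrl gave MHC class I -0.00839, B cells -0.33 and, by direction, muscle 0.0903. That fit gave muscle -0.25 for R+D against Ctrl, 0.14 for the difference by DOX and -0.0374 averaged, which the covariate itself removes. It gave MHC class I 0.00696 for R+D against R+X, T cells -0.0605 and cytotoxic effectors 0.12 for R+D against DPD, and skin 0.0581 for R+X against RP.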

Other observations

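The observations below were chosen after seeing the data and were not tested further.

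Pakap, the gene of the joined Palm2 and Akap2 locus on chromosome 4 (57434475 to 57896984, GRCm38), was near absent in both Ctrl libraries (1.41 and 1.07 CPM) and at 20.9 to 94.8 CPM in the 10 libraries of the treated groups (24.9 and 30.5 CPM in RP). Its log2 fold change against Ctrl was 4.91 ± 0.65 in DOX, 5.54 ± 0.66 in DPD, 4.69 ± 0.64 in R+X and 5.39 ± 0.66 in R+D, with edgeR adjusted p of 0.29, 0.119, 0.405 and 0.145. Akap2, which shares the locus, was at 99.3 and 64.9 CPM in Ctrl and 46.7 to 122.7 CPM elsewhere, and Palm2 at 0.743 to 2.16 CPM in all libraries. The sum of Pakap and Akap2 was 101 and 65.9 CPM in Ctrl and 76.2 to 161 CPM in the other libraries, so how reads were divided between the names was not resolved.

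Haemoglobin transcripts, summed, stood at 221.8 and 258 CPM in Ctrl and 366 and 345 in DOX. They stood at 123.3 and 24.8 in DPD, 50.3 and 86.9 in RP, 36.5 and 55.1 in R+X, and 21.3 and 32.4 in R+D.

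Skin keratinocyte and hair genes differed between libraries of the same group. Their mean was -1.22 and 2.90 in RP, 1.56 and -2.14 in DPD, -2.08 and 1.80 in R+D, and 1.24 and -1.04 in Ctrl on the centred log2 CPM scale. Within groups, list means that moved with that of skin included epithelial genes (r = 0.88), neutrophils (0.84), p53 targets (0.83) and inflammatory cytokines (0.71).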
